A study of Mus musculus with 11 samples.

How the data were processed

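Per the labels' protocols, GFP-positive macrophages were sorted from hearts of mice 2 to 3 months old, 100 ng of total RNA per sample was labelled with Cy3, and samples are independent biological replicates. Per the submitters' processing notes, images were read with Agilent Feature Extraction; its version is not given in the sources used here. The files used were 11 deposited gene-level scanner files and the authors' table. Per the file headers, each scanner file holds a total gene signal (intensity in scanner units, not log-transformed), its error and a detection flag of 0 or 1 for 1247 miRNAs and 21 controls. The authors' table holds log2 values, quantile normalized by the authors, for 317 miRNAs, which are those detected on at least 4 of 11 arrays. Within each array the authors' values ranked the 317 miRNAs in the order of the scanner values. miRNA names are printed without their species prefix, and suffixes such as _v19.0 are those of the files. The files name no genome build, so no coordinates are printed.

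The groups, comparisons, scaling, filter, tests, lists, rule for named miRNAs and first set of alternatives were fixed before the data were examined. Each array's total gene signal was divided by its 75th percentile over the 126 miRNAs detected on all arrays. The floor was the median over arrays of each array's lowest detected scaled signal (0.00271, a log2 of -8.53). Scaled signals under it were raised to it, and log2 was taken. miRNAs detected on at least 2 of 11 arrays were tested, which gave 369; 852 were never detected. The first plan counted all 11 arrays. Once seen, the files showed day 30 replicates 2 and 3 to differ by less than the scanner's error. They were averaged in log2 and counted as 1 sample, with 11 separate arrays as an alternative. Their squared difference was 0.208 times that expected, against 2.79 to 33.3 for the other 9 pairs.

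All groups entered 1 linear model in limma 3.58.1 under R 4.3.3 (files read with jsonlite 2.0.0), with 6 residual degrees of freedom, moderated t-tests for 6 comparisons and an F test across groups. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Lists were tested with camera at a preset correlation of 0.01 between members and again with an estimated one, adjusted over the lists of each comparison; lists needed 3 tested members. The 20 lists were written from general knowledge before the data were examined and hold 179 entries, some of them prefixes of names; 220 miRNAs on the array matched and 128 were tested. List counts leave out lower calls of miRNAs undetected in the group they fell from. Counts adjusted over the list alone repeat the adjustment within the list's members. The slide of each array was taken from the array layout of the deposited scanner files: slide 1 held day 0 replicate 1, day 3 replicates 1 and 3, day 7 replicates 1 and 3 and day 30 replicate 1, and slide 2 held the rest.

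For a miRNA undetected on every array of one group, no fold is printed except where one changed sign under an alternative. The bound divides the other group's mean by the lowest detected scaled signal of each array, averaged in log2 over the undetected group's arrays. On bright arrays this limit lies under the floor of the fit, so that a bound can exceed the fitted change. A lower call in a miRNA undetected on every array of the higher group was not read as a fall, since the scaled background of dim arrays lies above that of bright ones. For list medians with bounds, members of this kind were left out and undetected members entered at their bound.

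Named miRNAs were chosen by a fixed rule. In each comparison of 2 groups these were, among called miRNAs without overlap between groups and detected on every array of both, the 8 largest changes in each direction. To them were added the 4 largest bounds in each direction, up to 4 members per list (those called with the largest change, or the 2 of highest signal where none was called), and miR-155-5p, miR-146a-5p, miR-21a-5p, miR-223-3p and miR-142a-3p in every comparison. For the F test the rule took the 10 lowest p among miRNAs detected on all arrays. The text names fewer, in order of change, and miR-455-3p was named after its values were seen. The comparison of day 3 with the Ly6Clow mean had no such rule and is given as counts and lists.

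The tests, without the scaling, floor and filter, were tried on simulated data with the group sizes of day 3 against day 0. There were 369 miRNAs and 20 simulations with 30 changed miRNAs per fold. They called 18.5% of 2-fold, 74.8% of 4-fold and 95.2% of 8-fold changes and 0.911% of 269 unchanged miRNAs. A list of 10 planted 4-fold changes was called in 20 of 20 simulations and an unchanged list in 0, by a p not adjusted over lists. The simulated values held no difference in brightness, no detection limit, no slide and no correlation between list members. These rates therefore describe the tests on such values and not their yield or false calls on the real arrays.

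The alternatives fixed in advance were the percentile over all miRNAs, quantile normalization, no scaling, the authors' table, only miRNAs detected on all arrays, no filter, a floor of 0.5 or 2 times the main one, the slide as a block, each slide alone, a replicate block, trended and robust moderation, array weights, only the groups compared, a minimum fold of 2, an estimated correlation, signal above the floor as detection, and each replicate left out. Chosen after seeing the data were all 11 arrays as separate samples, a common floor at the highest of the arrays' lowest detected signals, scaling to the median of the miRNAs detected on all arrays or to the 4 dmr control features, cyclic loess over the miRNAs detected on all arrays, leaving out the 2 dimmest arrays, and array brightness (log2 of the scaling factor) as a covariate, which left 5 residual degrees of freedom, also together with an estimated correlation in camera. Neighbouring miRNA genes were found by name in a reference gene table, where 116 of the 126 miRNAs had a gene. Control features other than the dmr set entered no scaling and no test.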

Results

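MicroRNAs (miRNAs) were measured on 11 Agilent mouse miRNA arrays, each hybridised with Cy3-labelled RNA from GFP-positive cardiac macrophages of Cx3cr1GFP/+ mice, in which GFP is expressed from the fractalkine receptor locus. Cryoinjury, a freezing lesion of the heart wall, served as the model of myocardial infarction. Macrophages with the profile Ly6Clow/CX3CR1high came from hearts without surgery (day 0, 2 arrays) and from hearts at day 7 (3 arrays) and day 30 (3 arrays) after injury. Macrophages with the profile Ly6Chigh/CX3CR1low came from day 3 (3 arrays) and from no other day, so that stage and population cannot be told apart in any comparison with day 3. The labels describe independent biological replicates. The number of arrays limits the precision of every value.

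The arrays differed widely in brightness. The 75th percentile of the 126 miRNAs detected on all arrays was 55.7 to 163 scanner units at day 0, 805 to 1607 at day 3, 114 to 323 at day 7 and 1453 to 2304 at day 30, a 41.4-fold range. The 4 dmr control features, averaged on a log scale, spanned 2.16-fold over the same arrays. Within every group the arrays of slide 2 were dimmer than those of slide 1. A trend with brightness within groups, on which every fit with brightness rests, therefore cannot be fully parted from the slide. The total miRNA signal was 18432 to 26168 at day 0, 177260 to 288750 at day 3, 22368 to 71511 at day 7 and 234580 to 363860 at day 30. Of 1247 miRNAs on the array, 151 to 173 were detected at day 0, 301 to 338 at day 3, 208 to 270 at day 7 and 290 to 340 at day 30. A mean of 317.33 miRNAs was detected on the 3 day 3 samples and 242.57 on the 7 others, a difference of 74.8 that did not pass a two-sided exact permutation test (p = 0.133, 120 splits). With signal above a common floor in place of the scanner's detection flag the difference turned to -630.14 (exact p = 0.117), and all 1247 miRNAs lay above that floor on both day 0 arrays and on 2 day 7 arrays.

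**Figure D1:**
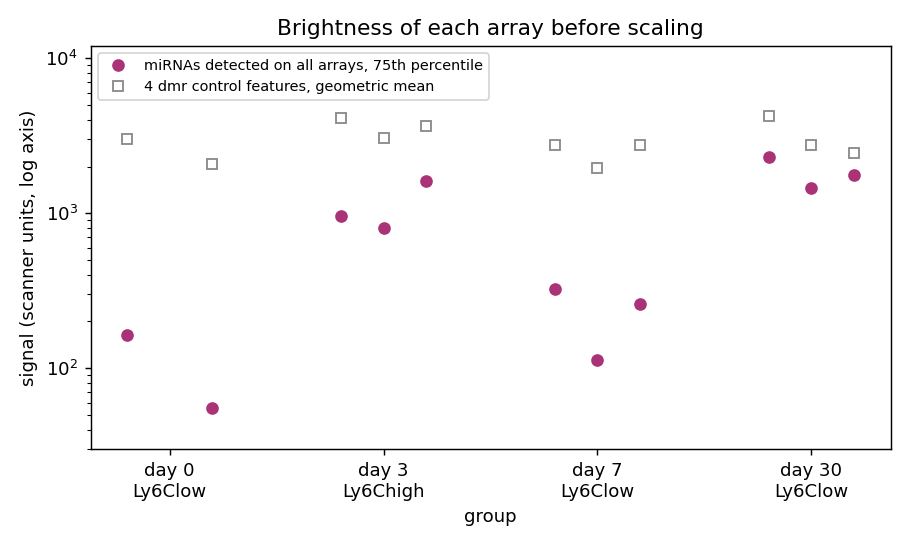
Brightness of each array before scaling, by group, on a log axis in scanner units; filled circles are the 75th percentile of the 126 miRNAs detected on all arrays and open squares the geometric mean of 4 dmr control features. The circles run from 55.7 at day 0 to 2304 at day 30, while the squares stay within a 2.16-fold range.

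Day 30 replicates 2 and 3 differed by less than the scanner's own error (median absolute log2 difference 0.06 over 290 miRNAs), whereas the other 9 pairs of replicates differed by more than it. They were averaged and counted as 1 sample, which left 2 samples at day 30 and 10 in all. Values below are log2 signals relative to the array's 75th percentile, given as mean ± SD over samples, and changes are differences of such means. On this scale the median change of the miRNAs detected on all arrays was not 0. It was -0.77 for day 3 against day 0, -0.21 for day 7 against day 0, -1.06 for day 30 against day 0, 0.63 for day 7 against day 3, -0.57 for day 30 against day 7 and -0.31 for day 3 against the Ly6Clow mean. Without scaling these medians were 2.73, 0.94, 3.26, -1.71, 2.61 and 1.36. All 124 changes that are named below as passing the test exceeded this shift in their own direction. This was largely fixed in advance, since a change opposite in sign to the shift always does so and the rule named the largest changes. Without scaling, named calls changed sign for 9 miRNAs at day 3 against day 0, 7 at day 30 against day 0 and 3 at day 7 against day 3.

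The first comparison asked how Ly6Chigh/CX3CR1low macrophages of day 3 after injury (n = 3) differed from Ly6Clow/CX3CR1high macrophages of the uninjured heart (n = 2). Brightness also separated these groups, with a 75th percentile of 805 to 1607 at day 3 and 55.7 to 163 at day 0. miR-21a-5p, a miRNA induced in many inflammatory and injury settings, rose from 0.92 ± 0.31 to 4.39 ± 0.10, a log2 change of 3.47 (SE 0.41, limma adjusted p = 0.000149). Several miRNAs fell. miR-99b-5p, miR-125a-5p and let-7e-5p, which come from a shared cluster, fell by 4.59 (adjusted p = 4.27e-05), 4.44 (adjusted p = 7.44e-05) and 3.12 (adjusted p = 0.000281). miR-146a-5p, an NF-kappaB-induced brake on Toll-like receptor signalling, went from -0.03 ± 0.49 to -4.62 ± 1.26 (adjusted p = 0.000357). miR-511-3p, encoded in an intron of the mannose receptor gene Mrc1, went from -1.98 ± 0.35 to -5.40 ± 0.48 (adjusted p = 0.0011).

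Other miRNAs detected on every array of both groups also moved. miR-125b-5p and miR-99a-5p fell by 3.29 and 3.09 (adjusted p = 0.000273 for both) and miR-30a-5p by 2.82 (adjusted p = 0.000672). Among those that rose were miR-142a-3p, a pan-haematopoietic miRNA (2.82, adjusted p = 0.00237), miR-10a-5p (2.35, adjusted p = 0.00115), miR-15b-5p (2.12, adjusted p = 0.0027), miR-1949 (1.98, adjusted p = 0.00819) and let-7i-5p (1.93, adjusted p = 0.00332). The myeloid miR-223-3p rose as well (3.87 ± 0.20 against 2.36 ± 0.61, adjusted p = 0.0112). Several miRNAs were undetected on both day 0 arrays and are given as bounds. miR-18a-5p was at least 10.9-fold higher at day 3 (adjusted p = 0.00102), miR-130b-3p at least 9.69-fold (adjusted p = 0.000353) and miR-7a-5p at least 7.79-fold (adjusted p = 0.0011). miR-222-3p was at least 6.78-fold higher (adjusted p = 0.00127) and miR-155-5p, induced by Toll-like receptor ligands, at least 2.68-fold (adjusted p = 0.0188). miR-328-3p was undetected on all 3 day 3 arrays and at least 21.4-fold lower (adjusted p = 0.000273).

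Of the 20 lists, the miR-17~92 cluster with its paralogous clusters, which are driven by Myc in dividing cells, was higher at day 3. It had 8 of 10 tested members higher and 0 lower, with a median of 2.23 (2.40 with undetected members at their bounds; camera adjusted p = 4.81e-05, adjusted p = 0.131 with an estimated correlation). Examples were miR-93-5p (2.48, adjusted p = 0.000987), miR-25-3p (2.05, adjusted p = 0.00273) and miR-106b-5p (3.15, adjusted p = 0.00218, detected on 1 of 2 day 0 arrays). The myeloid and pan-leukocyte list had 5 members higher and 1, miR-146a-5p, lower out of 8, with a median of 1.53 (1.47 with bounds; adjusted p = 0.042, adjusted p = 0.418 with an estimated correlation). The list of alternative macrophage activation had 6 of 10 members lower and 1 higher without passing the list test (median -2.46, adjusted p = 0.103; positive without scaling). The 6 included miR-99b-5p, miR-125a-5p, miR-511-3p and miR-146a-5p. The lists of let-7 (4 higher, 2 lower of 9, adjusted p = 0.143), Toll-like receptor and NF-kappaB response (4 higher, 2 lower of 9, adjusted p = 0.103) and miR-15/16 (3 higher of 6, among them miR-16-5p at 1.73; adjusted p = 0.103) did not pass either.

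Markers of other cell types were read beside these groups. miR-133a-3p and miR-133b-3p, the muscle miRNAs, fell by 2.81 and 2.75 (adjusted p = 0.000672 and 0.000881), so that 2 of 3 tested cardiomyocyte markers were lower (list adjusted p = 0.178; higher without scaling and with the dmr controls). The endothelial list had 1 member, miR-10a-5p, higher and 2 lower of 6 (adjusted p = 0.912). The fibroblast and smooth muscle list had 1 higher of 6 (adjusted p = 0.823) and the lymphocyte list 1 higher and 1 lower of 4 (adjusted p = 0.823). The epithelial, liver and neuron list had 0 of 5 (adjusted p = 0.763) and the erythroid list, with 2 tested members too short to test, 1 higher. The RNA quality list, miRNAs reported as fragments of longer RNA, had 4 of 13 lower, among them miR-709 (fell by 3.35, adjusted p = 0.000273; list median -1.36, adjusted p = 0.143; the median turned positive without scaling, with the percentile over all miRNAs and with the dmr controls). The Sfmbt2 intronic cluster had 7 lower and 2 higher of 17 (adjusted p = 0.364), among them miR-467f (fell by 3.52, adjusted p = 0.0011) and miR-669p-3p (fell by 3.46, adjusted p = 0.000852). The remaining lists were miR-232724 (1 higher of 6, adjusted p = 0.502), miR-29 (0 of 4, adjusted p = 0.668), miR-30 (2 lower of 7, adjusted p = 0.823), miR-181 (1 higher and 1 lower of 4, adjusted p = 0.502) and the imprinted Dlk1-Dio3 cluster (1 lower of 3, adjusted p = 0.178). The p53 and hypoxia list did not pass (1 higher of 5, the hypoxia-induced miR-210-3p at 2.37, detected on 1 of 2 day 0 arrays; adjusted p = 0.823). Adjusted over the list alone, the counts differed in Toll-like receptor and NF-kappaB response (5 higher), miR-30 (1 lower) and the epithelial, liver and neuron list (1 higher).

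**Figure D2:**
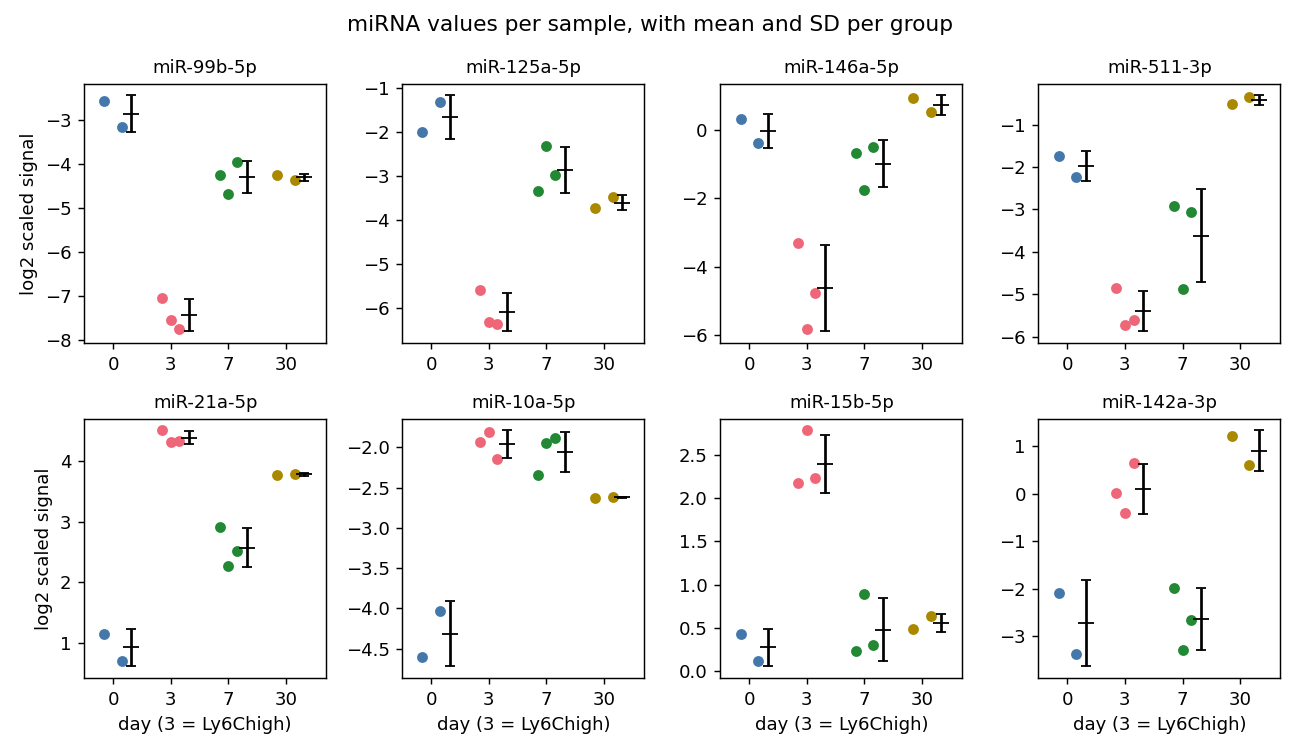
Log2 scaled signal of 8 named miRNAs by day (day 3 is Ly6Chigh, the other days Ly6Clow); points are samples and bars the mean with SD beside them. miR-99b-5p, miR-125a-5p, miR-146a-5p and miR-511-3p lie lowest at day 3 (-7.45, -6.11, -4.62 and -5.40), where miR-21a-5p lies highest (4.39); without scaling the day 3 value of miR-511-3p lies above that of day 0.

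In all, 204 of 369 tested miRNAs passed an adjusted p of 0.05 at day 3 against day 0 (60 higher, 144 lower; 225 at an unadjusted p under 0.05). Of the lower ones 80 were undetected on both day 0 arrays, where background sets the value, and are not read as falls; among miRNAs detected on every array of both groups 22 were higher and 52 lower. The groups did not overlap for 242 of the 369 tested miRNAs (chance gives 20%). This share is not read as beyond chance, since it takes in miRNAs undetected on both day 0 arrays, and brightness also separated the groups. With the array slide as a block 220 passed, and all 204 kept their sign within each slide. The groups did not overlap for 200 of the 204, which fixes that sign, so that it gives no separate support. Here miR-21a-5p changed by 3.28 and 3.62 within slides 1 and 2 and miR-99b-5p by -4.84 and -4.39. Within the slides the median of the miR-17~92 list was 1.65 and 2.15 (blocked adjusted p = 7.77e-05) and that of the myeloid list 1.10 and 1.36, whose call ended with the block (adjusted p = 0.0642). The split between higher and lower depended on scaling: 93 and 63 with quantile normalization, 86 and 116 with scaling to the median, 85 and 86 in the authors' table, 45 and 26 with the highest floor and 26 and 25 with cyclic loess. It was 189 and 4 with the percentile over all miRNAs, 250 and 1 without scaling and 235 and 3 with the dmr controls. Without scaling, miR-669p-3p, miR-511-3p, miR-709, miR-125b-5p, let-7e-5p, miR-30a-5p, miR-99a-5p, miR-133a-3p and miR-133b-3p came out higher rather than lower. With the dmr controls miR-30a-5p, miR-133a-3p and miR-133b-3p did.

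With array brightness as a covariate, a setting chosen after seeing the data, 68 miRNAs passed (53 higher, 15 lower), 34 of them also called without it. Of the 31 miRNAs named for this comparison 16 stayed called. These were miR-99b-5p, miR-125a-5p, miR-146a-5p, miR-511-3p, miR-125b-5p, miR-99a-5p and miR-30a-5p as lower. miR-21a-5p, miR-10a-5p, miR-15b-5p, miR-25-3p, let-7i-5p, miR-1949, miR-18a-5p, miR-130b-3p and miR-222-3p stayed as higher. miR-142a-3p and miR-16-5p turned to -0.17 and -0.62, and the miR-17~92 list no longer passed (median 1.68, adjusted p = 0.58). Of the other 13 without a call 11 were smaller, and miR-7a-5p and miR-155-5p were larger with larger standard errors (adjusted p = 0.0711 and 0.0837). Alternative activation (median -0.51, adjusted p = 0.00668, adjusted p = 0.615 with an estimated correlation) and the miR-30 family (median -1.99, adjusted p = 0.00499, adjusted p = 0.242 with an estimated correlation) then passed as lower. The myeloid list no longer passed, and the direction of camera was lower although its median was positive (0.62, camera adjusted p = 0.58). Leaving out day 0 replicate 2 gave 128 calls and ended those of miR-16-5p (adjusted p = 0.0819) and miR-223-3p (adjusted p = 0.0646). miR-155-5p lost its call without day 0 replicate 1 (adjusted p = 0.13) or day 3 replicate 1 (adjusted p = 0.0782). The number of lists was 5 without day 0 replicate 1 and 1 without day 3 replicate 1 or 3.

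The second comparison set Ly6Clow/CX3CR1high macrophages of day 7 (n = 3) against those of the uninjured heart (n = 2), the same sorted population. Few miRNAs passed the test. miR-10a-5p rose by 2.26 (limma adjusted p = 0.0227) and miR-21a-5p from 0.92 ± 0.31 to 2.57 ± 0.32 (1.65, adjusted p = 0.0393), while miR-30a-5p fell by 2.00 (adjusted p = 0.0281). Among miRNAs undetected on both day 0 arrays, miR-222-3p was at least 5.60-fold higher (adjusted p = 0.0227), the stromal miR-214-3p at least 5.46-fold, miR-1897-5p at least 4.19-fold and miR-1892 at least 3.81-fold (adjusted p = 0.0393 for all 3). miR-199a-3p (2.08, adjusted p = 0.0227) and miR-378a-3p, from an intron of Ppargc1b (1.63, adjusted p = 0.0393), were detected on 1 of 2 day 0 arrays. miR-455-3p, the other lower call, named after its values were seen, fell by 2.14 (adjusted p = 0.0281). miR-146a-5p (-0.96, adjusted p = 0.318), miR-223-3p (-0.83, adjusted p = 0.18), miR-142a-3p (0.08, adjusted p = 0.936) and miR-155-5p (undetected at day 0, adjusted p = 0.18) did not pass.

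No list passed camera with either correlation. At an unadjusted p under 0.05 there were 4 with the preset correlation and 0 with the estimated one. Toll-like receptor and NF-kappaB response came closest, with 2 of 9 members higher, 3 adjusted over the list alone (adjusted p = 0.0914, adjusted p = 0.857 with an estimated correlation). The fibroblast and smooth muscle list had 2 of 6 higher, miR-199a-3p and miR-214-3p (adjusted p = 0.14), the endothelial list 1 of 6 higher, miR-10a-5p (adjusted p = 0.691), and the RNA quality list 0 of 13 in either direction (adjusted p = 0.667). Adjusted over the list alone, alternative activation had 2 higher and 4 lower in place of 1 and 0, p53 and hypoxia 2 higher, miR-181 1 higher and let-7 1 lower in place of 0.

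In all, 14 miRNAs passed (12 higher, 2 lower; 135 at an unadjusted p under 0.05), 2 higher and 1 lower of them detected on every array of both groups. The groups did not overlap for 72 of the 369 tested miRNAs (chance gives 20%). All 14 kept their sign within both slides, which follows from the lack of overlap between the groups in all 14. With the slide as a block 24 passed, the 10 miRNAs named as called among them. The split was 27 higher and 9 lower with quantile normalization, 31 and 1 with scaling to the median, 12 and 5 with the highest floor, 15 and 7 in the authors' table and 7 and 3 with cyclic loess. It was 61 and 0 with the percentile over all miRNAs, 45 and 0 without scaling and 80 and 0 with the dmr controls. With brightness as a covariate 69 passed (47 higher, 22 lower), all 14 among them, and the miR-30 family passed as lower (median -1.55, adjusted p = 0.00457, adjusted p = 0.236 with an estimated correlation). With array quality weights or with only the 2 groups compared, 0 passed (77 and 24 at an unadjusted limma p under 0.05). The count was also 0 without day 3 replicate 2, day 3 replicate 3, day 7 replicate 3 or day 30 replicate 1 (125, 116, 38 and 109 at an unadjusted limma p under 0.05), 5 without day 3 replicate 1 and 9 without day 7 replicate 1. It was 43 without day 0 replicate 2, 114 without day 7 replicate 2 and 169 without day 0 replicate 1. As to lists, 2 passed without day 0 replicate 1 and 1 without day 0 replicate 2, day 7 replicate 2 or day 7 replicate 3.

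The third comparison asked how Ly6Clow/CX3CR1high macrophages of the healed heart at day 30 (n = 2) differed from those of the uninjured heart (n = 2). The day 30 arrays were the brightest and the day 0 arrays among the dimmest, with 0 day 0 or day 7 samples as bright as the dimmest day 30 sample, and with brightness as a covariate 0 of the 208 calls stayed (75 at an unadjusted limma p under 0.05). The changes between day 30 and day 0 cannot be told apart from brightness. Measured without that covariate, miR-142a-3p rose from -2.72 ± 0.91 to 0.91 ± 0.43 (3.63, limma adjusted p = 0.00129), miR-29b-3p, a repressor of collagens, from -2.71 ± 0.83 to 0.86 ± 0.32 (3.57, adjusted p = 0.00164). miR-21a-5p rose to 3.78 ± 0.02 (2.86, adjusted p = 0.000982). miR-19b-3p (2.68, adjusted p = 0.00532), miR-26b-5p (2.36, adjusted p = 0.012), miR-15a-5p (2.18, adjusted p = 0.00394), miR-29c-3p (2.14, adjusted p = 0.00685) and miR-27b-3p (2.09, adjusted p = 0.00591) rose as well. miR-494-3p, from the imprinted Dlk1-Dio3 cluster, fell from 1.55 ± 1.27 to -2.62 ± 0.37 (adjusted p = 0.000723).

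Further lower miRNAs were miR-721 (-4.55, adjusted p = 0.00394), miR-149-5p (-4.45, adjusted p = 0.000982), miR-6378 (-3.95, adjusted p = 0.00139), miR-702-3p (-3.88, adjusted p = 0.00173), miR-3085-3p (-3.88, adjusted p = 0.00188), miR-6360 (-3.85, adjusted p = 0.000723) and miR-467f (-3.70, adjusted p = 0.00154). miR-290a-3p and miR-3100-3p, undetected at day 30, were at least 41.5-fold (adjusted p = 0.00451) and 37.8-fold lower (adjusted p = 0.00356). Undetected on both day 0 arrays were miR-142a-5p, at least 18.0-fold higher at day 30 (adjusted p = 0.00153), miR-101a-3p, at least 11.5-fold (adjusted p = 0.00591), miR-19a-3p, at least 7.64-fold (adjusted p = 0.00255), and the erythroid miR-451a, at least 5.44-fold (adjusted p = 0.00532). miR-146a-5p (0.75, adjusted p = 0.38), miR-223-3p (0.32, adjusted p = 0.563) and miR-155-5p (undetected at day 0, adjusted p = 0.268) did not pass.

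Of the lists, 9 passed camera and 0 with an estimated correlation (4 at an unadjusted p under 0.05). With brightness as a covariate 0 passed. The medians of miR-232724 (-0.14), miR-29 (-0.25), miR-30 (-1.24), Toll-like receptor and NF-kappaB response (-1.19) and the Sfmbt2 cluster (0.56) then changed sign. Those of miR-17~92 (0.87), the myeloid list (0.20), miR-15/16 (0.93) and fibroblast and smooth muscle (1.97) kept theirs. In that fit the direction of camera was nevertheless lower for miR-17~92 and the myeloid list (camera adjusted p = 0.888 and 0.76). It was also lower for the Sfmbt2 cluster, against the sign of its median (camera adjusted p = 0.935). The list values that follow are from the fit without brightness. The miR-17~92 list had 6 of 10 higher (median 1.79, 1.91 with bounds; adjusted p = 0.000698, adjusted p = 0.0857 with an estimated correlation). The myeloid list had 4 of 8 higher (median 0.95; adjusted p = 0.000736, adjusted p = 0.0857 with an estimated correlation). The miR-15/16 family had 3 of 6 higher, 4 adjusted over the list alone (median 1.22; adjusted p = 0.000736, adjusted p = 0.0857 with an estimated correlation). The miR-29 family had 3 of 4 higher (median 1.65, 2.14 with bounds; adjusted p = 0.00398, adjusted p = 0.107 with an estimated correlation). The miR-232724 list had 1 of 6 higher (median 0.77, 0.68 with bounds; adjusted p = 0.00518, adjusted p = 0.177 with an estimated correlation). The miR-30 family had 1 of 7 higher, miR-30e-5p at 2.41 (detected on 1 of 2 day 0 arrays), and 0 adjusted over the list alone (median 0.33; adjusted p = 0.043, adjusted p = 0.177 with an estimated correlation). The Toll-like receptor and NF-kappaB list had 1 of 9 higher, miR-21a-5p (median 0.93, 0.88 with bounds; adjusted p = 0.00955, adjusted p = 0.24 with an estimated correlation). The Sfmbt2 cluster had 7 of 17 lower, 8 adjusted over the list alone, and 7 more that were undetected at day 0 (median -2.49, -3.25 over 8 members with those left out; adjusted p = 0.00398, adjusted p = 0.524 with an estimated correlation). This median was positive without scaling and with the dmr controls, and 0 with the highest floor. Beside these, the fibroblast and smooth muscle markers had 3 of 6 higher, among them miR-199a-3p (2.47, detected on 1 of 2 day 0 arrays) and miR-152-3p (at least 4.71-fold, adjusted p = 0.0121), with a median of 1.25 (1.99 with bounds; adjusted p = 0.00628, adjusted p = 0.24 with an estimated correlation). The RNA quality list had 8 of 13 lower, among them miR-709 (-3.17, adjusted p = 0.000982), without passing (median -2.37, adjusted p = 0.245, positive without scaling, with the percentile over all miRNAs and with the dmr controls), and 2 of 3 cardiomyocyte markers were lower (adjusted p = 0.797), higher under the same 3 scalings.

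In all, 208 miRNAs passed (33 higher, 175 lower; 236 at an unadjusted p under 0.05). Of the lower ones 89 were undetected on both day 0 arrays and are not read as falls; 13 higher and 58 lower were detected on every array of both groups. The groups did not overlap for 289 of the 369 tested miRNAs (chance gives 33.3%). The 289 include the 89 calls undetected on both day 0 arrays, and brightness also separated the groups, so that the share is not read as beyond chance. All 208 kept their sign within both slides, which follows from the lack of overlap between the groups in all 208 and gives no separate support. With the slide as a block 239 passed. Within the slides the list medians were 1.21 and 1.65 for miR-17~92 (blocked adjusted p = 0.000719), 1.25 and 2.06 for miR-29 (blocked adjusted p = 0.0032), 1.34 and 0.74 for fibroblast and smooth muscle (blocked adjusted p = 0.00765) and -1.74 and -3.23 for the Sfmbt2 cluster (blocked adjusted p = 0.00441). The other 5 called lists also passed with the block. The split was 106 higher and 84 lower with quantile normalization, 82 and 129 with scaling to the median, 83 and 87 in the authors' table, 38 and 30 with the highest floor and 30 and 35 with cyclic loess. It was 195 and 4 with the percentile over all miRNAs, 276 and 0 without scaling and 272 and 2 with the dmr controls. miR-494-3p, miR-6378, miR-702-3p, miR-3085-3p, miR-6360, miR-467f and miR-709 came out higher rather than lower without scaling, and the last 5 of them also with the dmr controls. With brightness as a covariate 0 of the 26 miRNAs named here as called stayed so and 14 changed sign, while the standard errors of all 26 grew. The other 12 kept their direction. The change was smaller for 8 of them, such as miR-21a-5p (1.80, SE 0.77, adjusted p = 0.238) and miR-199a-3p (2.38, SE 0.89, adjusted p = 0.204). It was larger for 4, miR-101a-3p, miR-19a-3p, miR-451a and miR-152-3p (adjusted p = 0.272, 0.204, 0.2 and 0.414), all undetected at day 0. Leaving out day 30 replicate 1 gave 102 calls and day 0 replicate 2 gave 115. miR-26b-5p and miR-30e-5p lost their calls without either (adjusted p = 0.0665 and 0.0956 for miR-26b-5p, 0.0791 and 0.136 for miR-30e-5p). miR-152-3p lost its call without day 30 replicate 1 (adjusted p = 0.0584) or day 0 replicate 1 (adjusted p = 0.0625), and miR-27b-3p without day 30 replicate 1 (adjusted p = 0.0538).

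The fourth comparison followed the step from day 3 (Ly6Chigh/CX3CR1low, n = 3) to day 7 (Ly6Clow/CX3CR1high, n = 3). It ran from bright to dim arrays, with a 75th percentile of 805 to 1607 at day 3 and 114 to 323 at day 7. Several miRNAs that had fallen at day 3 rose to day 7. miR-146a-5p rose from -4.62 ± 1.26 to -0.99 ± 0.68 (3.63, limma adjusted p = 0.00124), miR-125a-5p from -6.11 ± 0.43 to -2.88 ± 0.52 (3.23, adjusted p = 0.000517) and miR-99b-5p from -7.45 ± 0.37 to -4.30 ± 0.36 (3.15, adjusted p = 0.000517). miR-125b-5p (2.42, adjusted p = 0.00124), miR-99a-5p (2.07, adjusted p = 0.00177) and let-7e-5p (1.69, adjusted p = 0.00535) rose with them. miR-142a-3p fell from 0.10 ± 0.53 to -2.64 ± 0.66 (adjusted p = 0.00201), miR-223-3p from 3.87 ± 0.20 to 1.53 ± 0.30 (adjusted p = 0.00124) and miR-21a-5p by 1.82 (adjusted p = 0.0033).

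Other miRNAs that rose were miR-214-3p (2.79, adjusted p = 0.0033), miR-466f-3p (2.79, adjusted p = 0.00179), miR-721 (2.68, adjusted p = 0.019), miR-467f (2.67, adjusted p = 0.0033), miR-669p-3p (2.59, adjusted p = 0.00277) and miR-328-3p, undetected at day 3 and at least 7.98-fold higher at day 7 (adjusted p = 0.00224). Other miRNAs that fell were miR-98-5p (-2.17, adjusted p = 0.0031), miR-26b-5p (-2.13, adjusted p = 0.0112) and miR-15b-5p (-1.92, adjusted p = 0.00324). Undetected at day 7 were miR-1927, at least 9.09-fold lower (adjusted p = 0.000974), miR-340-5p, at least 8.68-fold (adjusted p = 0.00116), miR-3070-2-3p, at least 5.59-fold (adjusted p = 0.00177), and the epithelial miR-200c-3p, at least 5.50-fold (adjusted p = 0.00255). miR-155-5p did not pass (-0.61, adjusted p = 0.272).

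The miR-17~92 list fell, with 8 of 10 members lower, 9 adjusted over the list alone (median -1.94; adjusted p = 4.94e-06, adjusted p = 0.0849 with an estimated correlation). Its lower members included miR-18a-5p (-4.11, adjusted p = 0.000517, detected on 1 of 3 day 7 arrays), miR-106b-5p (-2.56, adjusted p = 0.00393), miR-19b-3p (-2.08, adjusted p = 0.00722) and miR-20b-5p (-2.01, adjusted p = 0.0183). The miR-15/16 family had 3 of 6 lower, 4 adjusted over the list alone, among them miR-15a-5p at -1.95 (median -1.36; adjusted p = 0.017, adjusted p = 0.315 with an estimated correlation). Alternative macrophage activation rose, with 5 of 10 members higher, 6 adjusted over the list alone (median 1.69, 1.78 over 9 members; adjusted p = 0.017, adjusted p = 0.34 with an estimated correlation). Its higher members were miR-125a-5p and miR-99b-5p of the shared cluster, miR-146a-5p, miR-511-3p of Mrc1 and the p53-induced miR-34a-5p, and its median turned negative without scaling. The RNA quality list rose as well, with 8 of 13 members higher, 10 adjusted over the list alone, among them miR-709 at 1.91 (median 1.57; adjusted p = 0.0174, adjusted p = 0.588 with an estimated correlation), and its median turned negative without scaling and with the dmr controls. Other markers moved too: 2 of 3 cardiomyocyte markers (adjusted p = 0.243), 2 of 6 endothelial (adjusted p = 0.522) and 2 of 6 fibroblast and smooth muscle markers (adjusted p = 0.299) were higher. The myeloid list had 4 of 8 lower and 1 higher, 5 and 1 adjusted over the list alone (adjusted p = 0.0539).

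In all, 137 miRNAs passed (78 higher, 59 lower; 205 at an unadjusted p under 0.05); 61 higher and 25 lower were detected on every array of both groups. The groups did not overlap for 237 of the 369 tested miRNAs (chance gives 10%, with samples taken as exchangeable, while brightness also separated these groups). All 137 kept their sign within both slides, which the lack of overlap between the groups fixed for 136 of them. With the slide as a block 203 passed. Within the slides the list medians were -1.59 and -2.69 for miR-17~92 (blocked adjusted p = 8.46e-06), 1.16 and 2.07 for alternative activation, -1.16 and -1.60 for miR-15/16 and 1.53 and 2.03 for RNA quality (blocked adjusted p = 0.0191 for all 3). The split was 121 higher and 65 lower with scaling to the median, 78 and 77 in the authors' table, 32 and 25 with cyclic loess, 69 and 79 with quantile normalization and 32 and 42 with the highest floor. It was 13 and 104 with the percentile over all miRNAs, 2 and 206 without scaling and 6 and 175 with the dmr controls. Without scaling miR-99a-5p, let-7e-5p and miR-709 came out lower rather than higher, as did let-7e-5p with the dmr controls. With brightness as a covariate 58 passed (8 higher, 50 lower), 34 of them shared. Of the 28 named miRNAs 11 stayed called, with miR-146a-5p, miR-125a-5p, miR-99b-5p, miR-125b-5p and miR-99a-5p as higher and miR-1927, miR-340-5p, miR-3070-2-3p, miR-200c-3p, miR-18a-5p and miR-15b-5p as lower. Of the other 17, 14 kept their direction with a smaller change, and miR-721, miR-26b-5p and miR-20b-5p turned to -1.11, 0.17 and 0.66 (adjusted p = 0.34, 0.841 and 0.4). Alternative activation then still passed (median 1.31, camera adjusted p = 0.00121, adjusted p = 0.519 with an estimated correlation). miR-17~92 (median -1.71, adjusted p = 0.0713), miR-15/16 (median -0.645, adjusted p = 0.587) and RNA quality (median 0.373, adjusted p = 0.0713) did not. The count was 82 without day 3 replicate 3, 89 without day 3 replicate 2, 86 without day 7 replicate 3 and 220 without either day 0 array. miR-721 and miR-20b-5p lost their calls without day 3 replicate 3 (adjusted p = 0.0764 and 0.0795) or day 7 replicate 2 (adjusted p = 0.0863 and 0.0763).

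The fifth comparison set day 30 (n = 2) against day 7 (n = 3) within Ly6Clow/CX3CR1high macrophages, from dim to bright arrays. With brightness as a covariate 13 miRNAs passed (12 higher, 1 lower), 6 of them shared with the 176 calls without it. Of the 29 miRNAs named here as called miR-101c and miR-340-5p stayed so (adjusted p = 0.00843 and 0.0313), while the standard errors of 28 grew. Of the other 27, 7 changed sign, 18 kept their direction with a smaller change, and 2 had a larger one, miR-101a-3p and miR-101b-3p_v20.0 (adjusted p = 0.0828 and 0.168). The 7 were miR-26b-5p (-0.29), miR-106b-5p (-0.28), miR-721 (0.72), miR-30e-5p (-1.02), miR-146a-5p (-0.19), miR-3100-3p and miR-290a-3p, the last 2 undetected at day 30 (adjusted p = 0.509 and 0.332). Measured without that covariate, miR-29b-3p rose by 3.95 (limma adjusted p = 0.00037), miR-142a-3p from -2.64 ± 0.66 to 0.91 ± 0.43 (3.55, adjusted p = 0.000482) and miR-511-3p from -3.62 ± 1.09 to -0.43 ± 0.11 (3.19, adjusted p = 0.00104). miR-19b-3p (3.27, adjusted p = 0.000856), miR-15a-5p (2.92, adjusted p = 0.00034), miR-29c-3p (2.89, adjusted p = 0.000856), miR-26b-5p (2.83, adjusted p = 0.00284) and miR-106b-5p (2.46, adjusted p = 0.00521) rose too. miR-494-3p fell by 4.49 (adjusted p = 0.000205), miR-6378 by 4.56 (adjusted p = 0.00034), miR-721 by 4.43 (adjusted p = 0.00164) and miR-1949 by 4.16 (adjusted p = 0.000205). miR-146a-5p (1.70, adjusted p = 0.0478), miR-21a-5p (1.21, adjusted p = 0.0262) and miR-223-3p (1.15, adjusted p = 0.0418) rose, and miR-155-5p did not pass (-0.25, adjusted p = 0.712).

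Undetected at day 7 were miR-101a-3p, at least 28.6-fold higher at day 30 (adjusted p = 0.000513), miR-101c, at least 12.6-fold (adjusted p = 0.00034), miR-340-5p, at least 12.4-fold (adjusted p = 0.000411), and miR-101b-3p_v20.0, at least 4.66-fold (adjusted p = 0.0124). Undetected at day 30 were miR-6354, at least 26.2-fold lower (adjusted p = 0.00137), miR-3100-3p, at least 23.9-fold (adjusted p = 0.00348), miR-290a-3p, at least 22.1-fold (adjusted p = 0.0065), and miR-450a-2-3p, at least 20.9-fold (adjusted p = 0.00104). miR-5105_v19.0 (-3.93, adjusted p = 0.000979), miR-6360 (-3.75, adjusted p = 0.000205), miR-3472 (-3.66, adjusted p = 0.00166) and miR-2137 (-3.64, adjusted p = 0.00034) fell as well.

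Of the lists, 7 passed camera and 0 with an estimated correlation (5 at an unadjusted p under 0.05). With brightness as a covariate 0 passed, and 0 did without scaling, in the authors' table, with the dmr controls or with cyclic loess. With brightness the medians of the Sfmbt2 cluster (0.805) and miR-232724 (-0.01) changed sign. Those of miR-30 (0.23), miR-17~92 (0.985), miR-15/16 (1.58), miR-29 (1.01) and the myeloid list (0.30) were smaller. For the myeloid list the direction of camera was then lower (camera adjusted p = 0.983). The list values that follow are from the fit without brightness. The miR-30 family had 5 of 7 higher, among them miR-30a-5p (2.41, adjusted p = 0.00104) and miR-30e-5p (2.71, adjusted p = 0.00678, detected on 2 of 3 day 7 arrays), with a median of 1.67 (1.48 with bounds). The miR-17~92 list had 6 of 10 higher (median 1.79), the miR-15/16 family 4 of 6 (median 1.76) and the miR-29 family 3 of 4, 4 adjusted over the list alone (median 2.16, 2.14 with bounds). These 4 lists had an adjusted p = 0.00174, and an adjusted p = 0.101 with an estimated correlation (0.102 for miR-17~92). The myeloid list had 5 higher and 1 lower of 8 (median 1.27; adjusted p = 0.00528, adjusted p = 0.11 with an estimated correlation) and miR-232724 2 of 6 higher (median 0.82; adjusted p = 0.0315, adjusted p = 0.322 with an estimated correlation). The Sfmbt2 cluster had 8 of 17 lower (median -1.16, -2.68 over 9 members; adjusted p = 0.0496, adjusted p = 0.643 with an estimated correlation), with a positive median without scaling and with the dmr controls and a median of 0 with the highest floor. Beside these, 9 of 13 members of the RNA quality list were lower, miR-5105_v19.0 and miR-2137 among them (median -1.98, adjusted p = 0.148, positive without scaling and with the dmr controls), 2 of 3 cardiomyocyte markers were lower and 1 higher (adjusted p = 0.981), and 2 of 6 fibroblast and smooth muscle markers were higher and 1 lower (adjusted p = 0.188).

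In all, 176 miRNAs passed (50 higher, 126 lower; 191 at an unadjusted p under 0.05); 27 higher and 85 lower were detected on every array of both groups. The groups did not overlap for 263 of the 369 tested miRNAs (chance gives 20%, with samples taken as exchangeable, while brightness also separated these groups). All 176 kept their sign within both slides, which follows from the lack of overlap between the groups in all 176. With the slide as a block 207 passed. Within the slides the list medians were 1.42 and 2.47 for miR-17~92 (blocked adjusted p = 0.00186), 2.20 and 2.61 for miR-29 (blocked adjusted p = 0.00147), 1.62 and 1.68 for miR-30 (blocked adjusted p = 0.00134) and -0.74 and -2.00 for the Sfmbt2 cluster (blocked adjusted p = 0.0397). The other 3 called lists also passed with the block. The split was 99 higher and 96 lower with quantile normalization, 66 and 121 with scaling to the median, 93 and 102 in the authors' table, 40 and 49 with the highest floor and 37 and 34 with cyclic loess. It was 126 and 45 with the percentile over all miRNAs, 234 and 10 without scaling and 226 and 20 with the dmr controls. Leaving out day 30 replicate 1 gave 110 calls and ended that of miR-101b-3p_v20.0 (adjusted p = 0.0937). miR-146a-5p, miR-21a-5p and miR-223-3p lost theirs without day 30 replicate 1 (adjusted p = 0.235, 0.155 and 0.226), day 7 replicate 2 (adjusted p = 0.151, 0.0606 and 0.0985) or day 7 replicate 3 (adjusted p = 0.0563, 0.0755 and 0.079). miR-146a-5p also lost it without day 3 replicate 3 (adjusted p = 0.0668), and miR-223-3p without day 3 replicate 1, 2 or 3 or day 7 replicate 1 (adjusted p = 0.0663, 0.0665, 0.0657 and 0.0514).

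The sixth comparison set the Ly6Chigh/CX3CR1low macrophages of day 3 (n = 3) against the mean of the 3 Ly6Clow/CX3CR1high groups. Alternative macrophage activation fell, with 6 of 10 members lower, 7 adjusted over the list alone (median -1.45; camera adjusted p = 0.0056, adjusted p = 0.437 with an estimated correlation). The 6 were miR-99b-5p, miR-125a-5p, miR-146a-5p, both arms of miR-511 and miR-34a-5p. The miR-17~92 list rose, with 7 of 10 members higher (median 1.66; adjusted p = 0.000215, adjusted p = 0.181 with an estimated correlation), among them miR-18a-5p, miR-93-5p and miR-25-3p. Within the slides the medians were -1.06 and -2.34 for alternative activation (blocked adjusted p = 0.00525) and 1.21 and 1.85 for miR-17~92 (blocked adjusted p = 0.000328). With brightness as a covariate alternative activation still passed (median -0.99, adjusted p = 0.00119, adjusted p = 0.402 with an estimated correlation) and miR-17~92 did not (median 1.55, adjusted p = 0.189). The miR-30 family (median -0.91, adjusted p = 0.00616), miR-232724 (median -0.75, adjusted p = 0.0354) and the cardiomyocyte markers (median -1.59, adjusted p = 0.0354) then passed as lower, but not with an estimated correlation (adjusted p = 0.315, 0.455 and 0.587). Beside these, 4 of 13 RNA quality members (adjusted p = 0.179, with a median that turned positive without scaling, with the percentile over all miRNAs and with the dmr controls) and 2 of 3 cardiomyocyte markers were lower in the fit without brightness (adjusted p = 0.169).

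In all, 137 miRNAs passed limma's test (58 higher, 79 lower; 180 at an unadjusted p under 0.05); 19 higher and 29 lower were detected on every array. All kept their sign within both slides, 158 passed with the slide as a block, and 111 with brightness as a covariate (87 higher, 24 lower), 58 of them shared. The split was 88 higher and 61 lower with quantile normalization, 72 and 82 with scaling to the median, 75 and 67 in the authors' table, 41 and 23 with the highest floor and 27 and 24 with cyclic loess. It was 149 and 31 with the percentile over all miRNAs, 208 and 24 without scaling and 182 and 36 with the dmr controls. The count was 87, 83 and 73 without day 3 replicate 1, 2 or 3 and 225 without day 0 replicate 1, where 1 list passed.

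**Figure D3:**
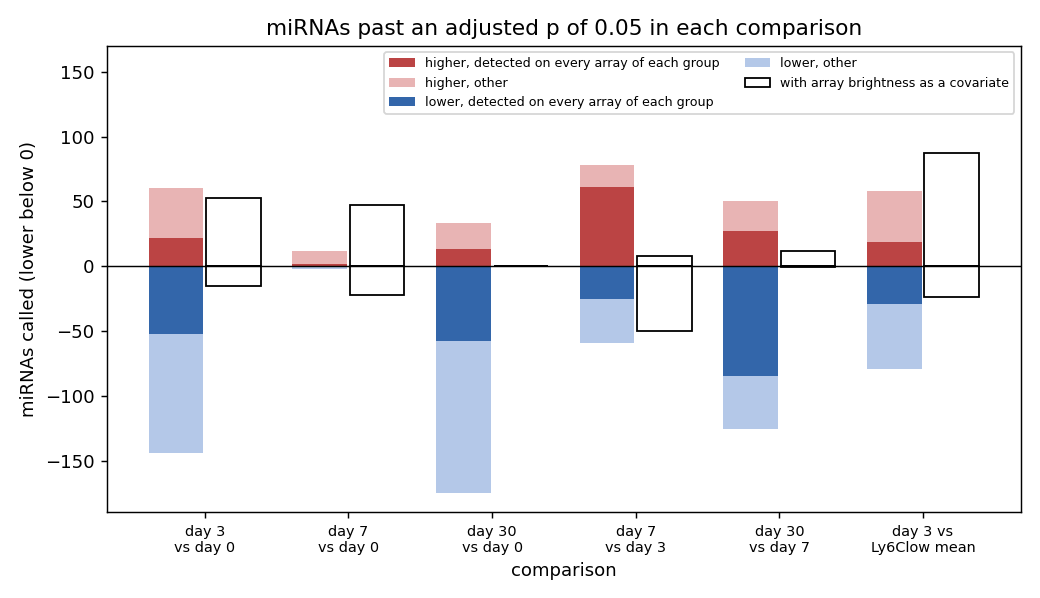
miRNAs past an adjusted p of 0.05 in each comparison, with higher ones above and lower ones below 0; filled bars show the counts, in dark shade those detected on every array of the groups compared, and open bars the counts with array brightness as a covariate. Day 30 against day 0 goes from 208 calls to 0 and day 7 against day 0 from 14 to 69.

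**Figure D4:**
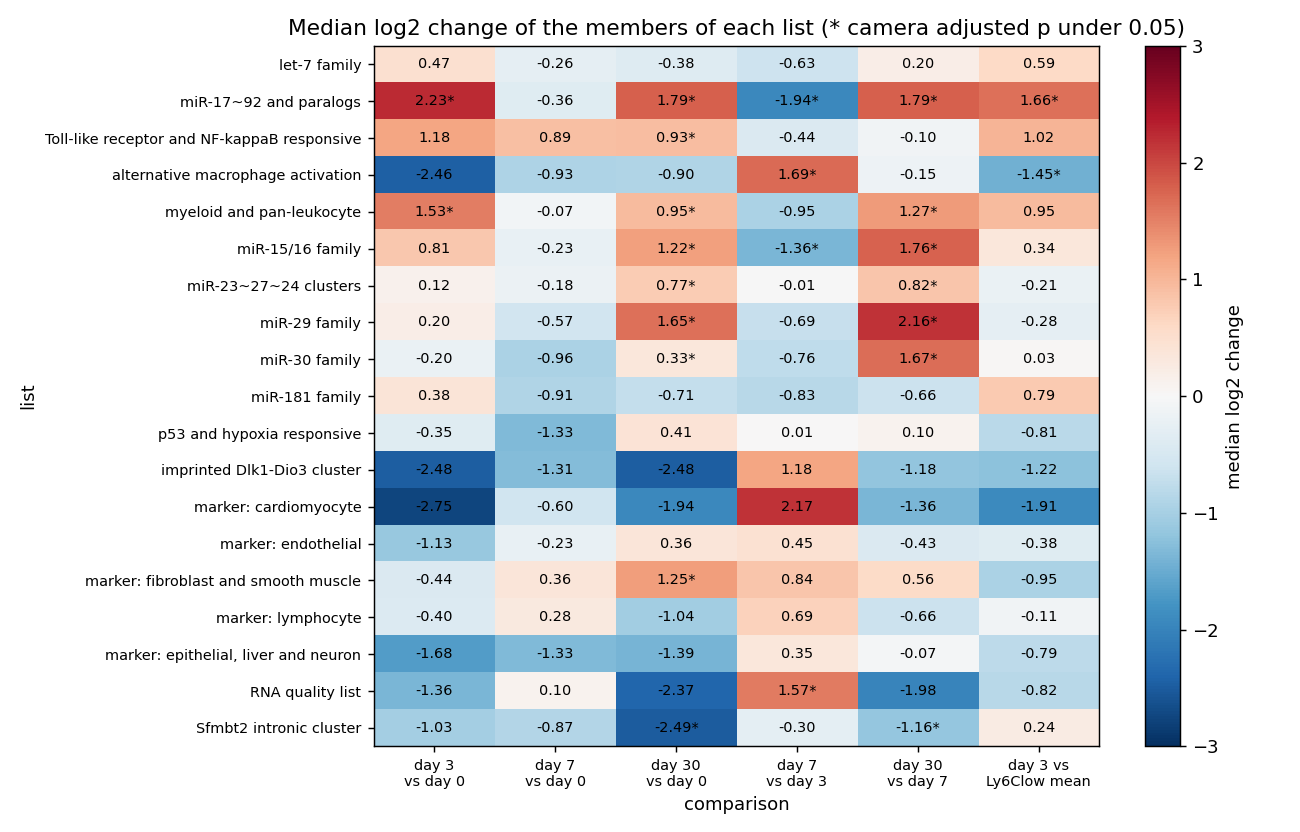
Median log2 change of the tested members of each list in each comparison; colour and number give the median, and an asterisk marks a camera adjusted p under 0.05 with the preset correlation. The miR-17~92 list has medians of 2.23, 1.79, -1.94, 1.79 and 1.66 in the 5 comparisons where it passes, and of the starred medians alternative activation and RNA quality at day 7 against day 3 and the Sfmbt2 cluster at day 30 change sign without scaling.

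Across all 4 groups, 291 of 369 miRNAs passed limma's F test, 93 of them among the 126 detected on all arrays. The 10 with the lowest p among these 126 had adjusted p-values between 0.000209 and 0.000349. miR-99b-5p went from -2.86 at day 0 to -7.45 at day 3, -4.30 at day 7 and -4.31 at day 30, and miR-125a-5p followed with -1.67, -6.11, -2.88 and -3.62. miR-99a-5p (-0.27, -3.35, -1.29 and -0.04), miR-146a-5p (-0.03, -4.62, -0.99 and 0.71), miR-511-3p (-1.98, -5.40, -3.62 and -0.43) and miR-30a-5p (-1.53, -4.36, -3.53 and -1.12) were also lowest at day 3. miR-21a-5p was lowest at day 0 (0.92, 4.39, 2.57 and 3.78). miR-1949 (-1.72, 0.27, 0.02 and -4.14), miR-494-3p (1.55, -0.30, 1.88 and -2.62) and miR-6360 (-1.97, -3.60, -2.06 and -5.81) were lowest at day 30, on the brightest arrays. The median, mean and camera direction differed in sign for several lists that did not pass, among them let-7 and alternative activation at day 30 against day 0 and the Sfmbt2 cluster at day 7 against day 3 (median -0.30, mean 0.44).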

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

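Of the tests weighed in this part, all were chosen only after the result was seen. miR-1949 differed between groups in opposite directions: against day 0 it was 1.98 higher at day 3 and 2.42 lower at day 30, a difference of -4.41 (SE 0.51, limma adjusted p = 0.000145). miR-3096b-3p_v19.0 did the same, 1.20 higher at day 3 (adjusted p = 0.0463) and 2.00 lower at day 30 (adjusted p = 0.00762), a difference of -3.20 (adjusted p = 0.000424). Fitted with brightness as a covariate, the day 30 changes were -0.08 (adjusted p = 0.963) and 0.13 (adjusted p = 0.941), while the day 3 changes were 3.87 (adjusted p = 0.0163) and 2.92 (adjusted p = 0.0287). Among control features that no comparison used, hur_2, hur_6 and mr_1 lay higher on all 9 arrays after injury than on both day 0 arrays, with ratios of the means of 2.37, 3.21 and 3.44. What these features measure was not established here. No group has the 4 to 10 samples needed to test whether a single sample stands apart.

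The first pattern weighed is the large set of changes at day 30. Across 126 miRNAs the change between day 30 and day 0 followed the trend with array brightness within groups at a correlation of 0.797, as high in 11 of 144 rearrangements of brightness within groups, and between day 30 and day 7 at 0.827, as high in 13 of 144. The slide 2 arrays were the dimmest of every group, so that this trend is mixed with the slide. It is also extended over log2 differences in brightness of 4.33 and 3.18 between the groups. The number of day 0 and day 7 samples as bright as the dimmest day 30 sample was 0, so stage after injury could not be examined at equal brightness. Array brightness and stage after injury therefore cannot be told apart as causes of this set. Single miRNAs differ: of 29 named calls at day 30 against day 7, 2 stayed with brightness as a covariate, 7 changed sign, and miR-101a-3p and miR-101b-3p_v20.0 lost theirs with a larger change (adjusted p = 0.0828 and 0.168), so that a lost call alone does not speak for brightness.

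The second pattern is the low level of miR-99b-5p, let-7e-5p, miR-125a-5p, miR-99a-5p, miR-125b-5p, miR-146a-5p and miR-511-3p at day 3. Against the Ly6Clow mean their median change was -3.39, and -3.12 with brightness as a covariate, with 7 of 7 called. Against day 0 let-7e-5p lost its call in that fit (-1.72, limma adjusted p = 0.072). Without scaling let-7e-5p, miR-99a-5p, miR-125b-5p and miR-511-3p came out higher at day 3 than at day 0. The 7 were chosen after the results were seen, and other falls against day 0 shrank with brightness, such as miR-467f (-3.52 to -0.39). Whether array brightness gave part of the pattern is therefore not settled by this fit. Loss of endothelial cells sorted along with the macrophages, a hypothesis from the marker list, would lower miR-126a-3p. It changed by 0.303 (SE 0.501) at day 3 against the mean of day 7 and day 30, where the median of the 7 was -2.86. The level of miR-126a-3p was -2.61, -1.51, -1.66 and -1.96 at days 0, 3, 7 and 30. Of the same list, miR-99a-5p, itself among the 7, and miR-100-5p fell at day 3 against day 0 (-3.09 and -1.89, limma adjusted p = 0.000273 and 0.00809). miR-10a-5p of that list rose (2.35, limma adjusted p = 0.00115). The endothelial markers thus went both ways, and miR-126a-3p alone does not settle this hypothesis. Loss of cardiomyocytes stays open, since miR-1a-3p was detected on 1 of 5 day 0 and day 7 arrays, on 2 of 3 day 3 arrays and on 3 of 3 day 30 arrays, while miR-133a-3p and miR-133b-3p fell at day 3; of 6 cardiomyocyte markers 3 were tested and 0 belong to another list, the cardiomyocyte list passed as lower with brightness as a covariate (median -1.59, adjusted p = 0.0354, adjusted p = 0.587 with an estimated correlation), and the sort for GFP in Cx3cr1GFP/+ hearts should remove such cells. Sorted population and stage cannot be told apart, since 0 samples share the population or the day of the day 3 samples but not both.

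The third pattern is the excess of lower calls against day 0 at day 3 (70.6% of the calls) and day 30 (84.1%), which day 7 did not show (14.3%, and 29.4% with the common highest floor). With that floor 36.6% of the calls at day 3 and 44.1% at day 30 were lower. Of the lower calls without it, 80 of the 144 and 89 of the 175 were of miRNAs undetected on both day 0 arrays. A floor at the level of the dimmest array works against such calls by its construction and cuts falls on bright arrays. Quantile normalization also turned the split (93 higher and 63 lower at day 3, 106 and 84 at day 30). Whether background of dim arrays gave the excess is therefore not settled by this floor. Among miRNAs detected on every array of both groups 22 were higher and 52 lower at day 3, and 13 and 58 at day 30. Of these, 18 and 19 at day 3 and 11 and 20 at day 30 stayed called in the same direction with quantile normalization, scaling to the median, the highest floor and in the authors' table alike. On the main scale the median change of the miRNAs detected on all arrays was itself -0.77 at day 3 and -1.06 at day 30. It was -0.25 and -0.26 with scaling to the median and 2.73 and 3.26 without scaling. Without scaling 250 of all tested miRNAs were called higher and 1 lower at day 3, and 276 and 0 at day 30. The excess of lower calls therefore depended on the scaling. No scaling was shown to be the right one, so whether more miRNAs fell than rose stays open.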

How the results depend on the processing

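Comparisons are given in the order day 3 against day 0, day 7 against day 0, day 30 against day 0, day 7 against day 3, day 30 against day 7 and day 3 against the Ly6Clow mean, then the F test, unless named. The reported counts of called miRNAs were 204, 14, 208, 137, 176, 137 and 291, and of lists 2, 0, 9, 4, 7 and 2. Over 133 named changes and 33 alternatives, left-out replicates among them, 3839 values counted as the same and 338 kept direction but were no longer called. The same meant that direction and side of the threshold were kept. For 74 of the 3839, from slide 2 only and without a test, it meant a change within the miRNA's residual SD. A further 29 became called, 59 without a test moved (slide 2 only) and 26 changed sign, all 26 with brightness as a covariate. This tally was partly fixed in advance. The groups did not overlap for the named calls, so that leaving out a replicate or keeping 1 slide could not reverse their sign. Leaving out an array of a group not compared left the change itself as it was, and only its test could differ. In the numbers of this tally, changes under no scaling and under scaling to the median, to the dmr controls or to the percentile over all miRNAs are taken relative to how far that scaling moved the median of the miRNAs detected on all arrays. The side of the threshold is that of the test without this correction. Taken as they stand, named calls changed sign without scaling for 9 miRNAs at day 3 against day 0, 7 at day 30 against day 0 and 3 at day 7 against day 3, and with the dmr controls for 3, 5 and 1. Unless said otherwise the cause was not tested.

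With only miRNAs detected on all 11 arrays, which tests fewer, the counts were 73, 4, 81, 75, 80, 59 and 104, and the lists 1 for day 3 against day 0, 5 for day 30 against day 0 and 4 for day 30 against day 7. With no filter, where miRNAs detected nowhere are called from scaled background, counts were 1110 for day 3 against day 0, 1011 for day 7 against day 0, 1109 for day 30 against day 0, 790 for day 7 against day 3, 834 for day 3 against the Ly6Clow mean and 1190 for the F test, and lists 12, 10, 14, 10, 12 and 7. With the common highest floor, chosen after seeing the data, counts were 71 for day 3 against day 0, 68 for day 30 against day 0, 74 for day 7 against day 3, 89 for day 30 against day 7, 64 for day 3 against the Ly6Clow mean and 117 for the F test. With a floor 2 times the main one the count was 88 for day 3 against the Ly6Clow mean. With cyclic loess over miRNAs detected on all arrays, also chosen after seeing the data, counts were 51 for day 3 against day 0, 65 for day 30 against day 0, 57 for day 7 against day 3, 71 for day 30 against day 7, 51 for day 3 against the Ly6Clow mean and 92 for the F test, with 0 lists for day 30 against day 0 and 0 for day 30 against day 7 (4 and 4 at an unadjusted camera p under 0.05).

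With the 75th percentile over all miRNAs, day 7 against day 0 had 61 calls, and lists were 1 for day 3 against day 0, 1 for day 30 against day 0 and 1 for day 3 against the Ly6Clow mean. With quantile normalization, day 7 against day 0 had 36 calls, and lists were 3 for day 30 against day 0 and 4 for day 30 against day 7. With no scaling between arrays, calls were 45 for day 7 against day 0, 208 for day 7 against day 3 and 232 for day 3 against the Ly6Clow mean, and lists 1 for day 3 against day 0, 1 for day 30 against day 0, 2 for day 7 against day 3, 0 for day 30 against day 7 (5 at an unadjusted p under 0.05) and 1 for day 3 against the Ly6Clow mean. In the authors' processed table, day 7 against day 0 had 22 calls, and lists were 5 for day 30 against day 0 and 0 for day 30 against day 7 (8 unadjusted). Scaled to the median over miRNAs detected on all arrays, day 7 against day 0 had 32 calls and day 3 against day 0 had 1 list. Scaled to the dmr control features, calls were 80 for day 7 against day 0 and 218 for day 3 against the Ly6Clow mean, and lists 1 for day 3 against day 0, 1 for day 30 against day 0, 2 for day 7 against day 3, 0 for day 30 against day 7 (7 unadjusted) and 1 for day 3 against the Ly6Clow mean. The last pair of scalings was chosen after seeing the data.

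With an estimated inter-gene correlation in camera, lists were 0 for day 3 against day 0, 0 for day 30 against day 0, 0 for day 7 against day 3, 0 for day 30 against day 7 and 0 for day 3 against the Ly6Clow mean (2, 4, 2, 5 and 2 at an unadjusted p under 0.05). With the slide as a block, day 7 against day 0 had 24 calls and day 3 against day 0 had 1 list. With arrays of slide 1 only, calls were 38 for day 7 against day 0 and 88 for day 30 against day 0; slide 2 only left no residual degrees of freedom and gave values without a test. With array quality weights, calls were 100 for day 3 against day 0, 0 for day 7 against day 0 (77 at an unadjusted limma p under 0.05), 275 for day 7 against day 3 and 303 for day 30 against day 7, with 1 list for day 7 against day 0. With only the groups compared, day 7 against day 0 had 0 calls (24 at an unadjusted limma p under 0.05); this setting does not apply to day 3 against the Ly6Clow mean. Leaving out the 2 dimmest arrays, chosen after seeing the data, gave 53 calls for day 7 against day 0 and 214 for day 7 against day 3. With all 11 arrays as separate samples counts were 221, 18, 240, 154, 201, 157 and 325. Detection by signal above the floor turned the difference in detected miRNAs to -630.14, since background of dim arrays lies above that floor.

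The replicate block gave 205, 12, 226, 165, 179, 135 and 296 calls and 1 list for day 3 against day 0, and moved no other count by over 1.5 times. With group means removed, samples of different groups with the same replicate number correlated at a median of 0.44 (13 pairs) and others at -0.365 (24 pairs). Samples of the same slide correlated at a median of 0.44 (19 pairs) and of different slides at -0.44 (18 pairs). In a group of 2 samples the remainders are mirror images, such as -0.109 and 0.109 for day 0 replicates 1 and 2 against day 3 replicate 1. The signs are therefore partly arithmetic. All 13 pairs with the same number also shared a slide, so that pairing by number cannot be told apart from the slide.

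With array brightness as a covariate, chosen after seeing the data, calls were 68 for day 3 against day 0, 69 for day 7 against day 0, 0 for day 30 against day 0 (75 at an unadjusted limma p under 0.05), 58 for day 7 against day 3 and 13 for day 30 against day 7, and lists 1 for day 7 against day 0, 0 for day 30 against day 0 (1 unadjusted), 1 for day 7 against day 3, 0 for day 30 against day 7 (3 unadjusted) and 4 for day 3 against the Ly6Clow mean. With an estimated correlation as well, no list passed in any comparison. Changes of sign were, for day 3 against day 0, miR-142a-3p -0.17 and miR-16-5p -0.62. For day 30 against day 0 they were miR-142a-3p -0.073, miR-29b-3p -0.49, miR-19b-3p -0.53, miR-26b-5p -1.89, miR-29c-3p -0.38, miR-27b-3p -0.16, miR-721 2.46, miR-149-5p 0.21, miR-702-3p 1.12, miR-3085-3p 1.24, miR-467f 0.18, miR-290a-3p 2.29, miR-3100-3p 1.80 and miR-30e-5p -2.67. For day 7 against day 3 they were miR-721 -1.11, miR-26b-5p 0.17 and miR-20b-5p 0.66. For day 30 against day 7 they were miR-26b-5p -0.29, miR-106b-5p -0.28, miR-721 0.72, miR-3100-3p 0.92, miR-290a-3p 1.49, miR-30e-5p -1.02 and miR-146a-5p -0.19.

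Leave-one-out counts ran from 128 to 240 for day 3 against day 0, 0 to 169 for day 7 against day 0, 102 to 263 for day 30 against day 0, 82 to 220 for day 7 against day 3, 110 to 208 for day 30 against day 7, 73 to 225 for day 3 against the Ly6Clow mean and 223 to 334 for the F test. Lists ran from 1 to 5, 0 to 2, 7 to 10, 4 to 5, 5 to 7 and 1 to 2. Where a group was left with 1 sample, that sample was assumed to vary like those of the other groups. Signal over background limits all comparisons with day 0 and day 7, whose arrays detected 151 to 270 miRNAs against 290 to 340 elsewhere: a miRNA low in signal there could be bounded but not measured, and whether it fell could not be seen.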

Other observations

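Of the tests in this part, the one on splits that keep the slides was chosen only after the result was seen; the neighbour test and the 4 tests on other splits were fixed before. Of the miRNAs called higher against the uninjured heart, 25 at day 3, 7 at day 7 and 10 at day 30 were undetected on both day 0 arrays. The first principal component of the samples held 64.2% of the variance and the second 25.8%. On the first, the samples of the dim groups, day 0 and day 7, had negative values (-16.1 to -3.11). Those of the bright groups, day 3 and day 30, had positive values (3.88 to 14.4). Group and brightness were not told apart on it.

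Neighbouring miRNA genes were asked whether they vary together, as shared transcription would have it. Over 24 pairs within 10 kb, with group means removed, the median correlation was 0.35, against a median of 0.116 in 10000 random pairings whose middle 90% ran from -0.311 to 0.529 (one-sided permutation p = 0.176). Shared transcription of neighbouring genes was not seen by this test. Group means were removed but slide and brightness were not, and both can make unrelated miRNAs vary together, so that the test does not speak against it.

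Other splits of the samples were fitted in the same way. For day 7 against day 3, in a fit of these 2 groups alone, the real split gave 201 called miRNAs, as many as 1 of 10 splits, which is the real one, and the highest other gave 0; with 10 splits chance cannot be excluded at a share under 0.05. The real split gave 4 lists, reached by 4 of 10 splits with 5 as the highest other, so chance cannot be excluded for the lists. For day 3 against the other 7 samples as 1 group, the real split gave 25 calls, reached by 4 of 100 splits that ignored the slide; the highest other gave 113 and set apart day 0 replicate 2 and day 7 replicates 2 and 3, among the dimmest arrays. Among splits that set apart as many samples of each slide as the real one, 3 of 60 reached 25 calls, with 73 as the highest other. That split set apart the 3 brightest samples (day 3 replicate 3 and both samples of day 30), and other splits carry differences of group and brightness of their own, so that neither count settles whether chance gave the calls at day 3. The real split gave 2 lists, reached by 76 of 100 splits with 11 as the highest other, so chance cannot be excluded for these lists.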
